A study of Gasterosteus aculeatus with 31 samples.

How the data were processed

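The data are ATAC-seq libraries of the left or right brain side of 31 juvenile threespine stickleback, 16 father-reared and 15 orphaned. Tissue was cryopreserved as homogenate, transposed with Tn5, amplified by PCR and sequenced, in library batches whose members are not given, per the labels' protocols. The submitters' processing notes name FastQC 0.11.8, Bowtie2 2.3.5.1, SAMtools 1.9, Picard 2.10.1, MACS2 2.2.5 and DiffBind 3.14.0, without their roles or settings. Whether reads were shifted for the transposase offset, how duplicates were treated and which genome build was used are not given in the sources used here.

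The authors deposited 1 table of raw counts, whole numbers of reads per peak and library with no normalization, for 102149 peaks shared by all libraries. Of these, 101044 have a start and stop 400 apart, the widest spans 1173, and 31 have a start below 1, as fixed windows placed near the end of a sequence would. Peak sets called on the same libraries hold few peaks that are absent from all of them, and PCR reads without molecular identifiers are not independent molecules. The gene table at hand belongs to another assembly (fGasAcu3.hap1.1), whose genes extend past the last peak on all 21 linkage groups, so it was not used to name peaks. The 16 gene lists fixed before the data were examined, and the share of counts near transcription start sites, were therefore not analysed here.

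Care group, sex and brain side were taken from the labels. Family was read from the leading number of the fish identifier, which is an inference; the labels call the design a half-sib one without listing families. Library numbers were split into 3 stretches of 11 numbers as candidate batches. Care was given to families, so siblings are not independent replicates of care; the consensus correlation of siblings within peaks was 0.0386 to 0.042. A fit with family as a random replicate block called 0 peaks for care, as did a fit on counts summed per family.

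Peaks were filtered with edgeR's filterByExpr (minimum count 10, 4 care-by-sex groups), which removed 1341 and left 100808. Counts were scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F tests, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Care and sex came from a model with both terms, care in each sex and the interaction from a model of 4 group means, and side from a model with sex and care. Log2 differences are father-reared minus orphaned, male minus female and left minus right, and SEs follow from the F statistic. CPM values use TMM-scaled library sizes, with a prior count of 2 for log2 CPM. The 95% intervals cover the model's error and take fish as independent. The median peak had 20 to 73 counts per library.

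Shares of counts were compared by exact permutation over the splits of the 16 families for care and by exact sign flips over 15 families for sex. Sibling similarity used 100000 permutations of families within sex and care. groupXIX windows of 1 Mb and 100 kb with at least 5 peaks were scaled to counts off groupXIX. Peaks named in the text follow a rule set before the data were examined: the 10 with the lowest raw p where fewer than 10 passed, for sex the 5 highest and 5 lowest log2 values among peaks past the threshold with a mean of at least 1 CPM, on and off groupXIX separately, and for side the 5 with the lowest raw p. The part of the rule that skips further peaks of a gene, and the part for gene lists, could not be applied. The other peaks named were chosen after their values were seen: those that passed only with a library left out, and those in the plot of male-higher peaks.

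The fits were tested on simulated counts drawn from the real means, library sizes and trended dispersions, independently for each fish. The draws held no likeness of siblings, no spread particular to a peak and no trend of libraries with peak strength. Recovery in the real libraries may therefore be lower. In the draws, 200 peaks were changed by 1.25-, 1.5- or 2-fold. For care over all fish, 13.4%, 88.1% and 100% of these were recovered, with 9 other calls among 100685 peaks. In males 1.49%, 44.8% and 97.0% were recovered, in females 2.99%, 52.2% and 98.5%, and for the interaction 0%, 10.4% and 65.2%.

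Alternatives set before the data were examined were DESeq2 1.42.0 (its dispersion trend by local regression), RLE size factors, no scaling factors, no filter, a mean of at least 2 CPM, a threshold of 0.10, each library left out, brain side, library stretch or 1 surrogate variable (sva 3.50.0) as covariates, no sex term, family sums, family as a random (limma 3.58.1) or fixed replicate block, and groupXIX left out. Those added after seeing the data were a robust variance prior, removal of each library's trend with peak strength (loess span 0.3), and father-reared replicates 7 and 12 left out together. Sums over larger regions, the share of counts in the strongest peaks with its cutoffs, and each family left out were also added then. So were the 500 most variable peaks, centring by sex and adjustment of the sex p values over peaks off groupXIX alone. Fits with a library left out, and 100 random splits per comparison, kept the trended dispersion of the full fit. Figures were drawn with Python and matplotlib.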

Results

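Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in brains of juvenile threespine stickleback (Gasterosteus aculeatus). In this fish the father alone tends the eggs and fry. The offspring of wild-caught fathers were either raised by the father (father-reared, given as Day 10 in the labels) or hand-reared without him (orphaned, Day 0). Before sexual maturity each fish met a model sculpin, a predatory fish, moved through an open arena, and its brain was taken after that simulated attack. The left or the right side of each brain went into a library.

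There were 31 libraries, 1 per fish: 16 father-reared fish (8 males and 8 females) and 15 orphaned fish (7 males and 8 females). Fish identifiers that share their leading number were read here as 1 family, which gave 8 father-reared and 8 orphaned families. Of these 16 families, 15 contributed 1 male and 1 female and 1 orphaned family a single female. The table held counts for 102149 peaks, of which 93652 lay on the linkage groups groupI to groupXXI and 8497 on 667 scaffolds. Total counts per library ran from 2857578 to 10540612 with a median of 4424554, and the median peak had 20 to 73 counts depending on the library. No pair of libraries was identical, and pairwise correlations of log2 counts across peaks lay between 0.775 and 0.926. Peaks are given by sequence, start and stop as the file gives them. The genome build is not given in the sources used here, so no gene, exon or promoter is assigned to any peak.

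The main question of the design was whether care by the father left a difference in brain chromatin. No peak passed the test of care among the 100808 peaks tested. The fit takes fish as independent although care was given to families, so its intervals may be too narrow. In it, the 95% interval of the father-reared to orphaned ratio lay within 1.5-fold in either direction for 98.6% of peaks. For 99.9% it lay within 2-fold. The median absolute log2 difference was 0.09 with a median 95% half-width of 0.21. The 10 peaks with the lowest raw p differed by log2 values from -0.57 to 0.93, and none of them passed.

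Among those 10 peaks, groupVI 4973594 to 4973994 had 5.80 ± 2.08 CPM (SD, n = 16; CPM are counts scaled to library size) in father-reared and 8.44 ± 1.23 CPM (n = 15) in orphaned fish, a log2 difference of -0.57 (SE 0.11, edgeR adjusted p = 0.38). The peak at groupII 14550436 to 14550836 had 13.4 ± 3.88 CPM (n = 16) against 8.92 ± 2.53 CPM (n = 15), a log2 difference of 0.60 (SE 0.12, edgeR adjusted p = 0.38). At groupI 19249555 to 19249955 the log2 difference was -0.51 (SE 0.11) and at groupI 22355322 to 22355722 it was -0.48 (SE 0.10). The peaks at groupII 2828781, groupVII 8625479, groupI 7088644, groupVII 6676227, groupXII 7674528 and scaffold_185 7570 were higher in father-reared fish by log2 values of 0.41, 0.54, 0.50, 0.40, 0.56 and 0.93. Their edgeR adjusted p values ran from 0.39 to 0.52.

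At a raw p under 0.05 there were 7303 peaks (7.24% of those tested), 3615 higher and 3688 lower in father-reared fish, and the lowest edgeR adjusted p was 0.38. DESeq2 also called 0 peaks, with 7530 at a raw p under 0.05 and a lowest adjusted p of 0.064. Counts summed over 573 regions, 1 Mb windows of the linkage groups and whole scaffolds, gave 0 regions (lowest adjusted p 0.74), and sums over 22 units, the 21 linkage groups and all scaffolds together, also gave 0 (lowest adjusted p 0.35). In simulated counts drawn independently for each fish, with no spread particular to a peak, the same test recovered 88.1% of peaks changed 1.5-fold. Without father-reared replicate 3 the test called 3 peaks, all lower in father-reared fish (scaffold_61 897443, scaffold_95 140288 and scaffold_95 143379). At the scaffold_95 peaks orphaned replicate 15 had 510 and 468 CPM, against medians of 15.4 and 13.1 CPM over all fish. Without father-reared replicate 8 or 13 the test called groupVI 4973594. Without orphaned replicate 7 the test called scaffold_89 10177, where that fish had 22.2 CPM.

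The care difference followed peak strength without passing a test. Peaks in the strongest 10% by mean CPM had a median log2 difference of 0.13, and those in the weakest 10% -0.05. The trend was not particular to care: for males minus females the medians were 0.07 and -0.03. Of the strongest 10%, 1271 peaks were higher and 15 lower in father-reared fish at a raw p under 0.05. The share of counts in the strongest 10% was a measure chosen after the data were seen. The strongest 10% held 31.3% ± 2.72 of the counts in father-reared families (SD, n = 8) and 29.4% ± 1.53 in orphaned families (SD, n = 8), a difference of 1.92 percentage points (two-sided exact permutation p over family means = 0.102, adjusted p over 4 library measures = 0.204). It was 1.21 without the family of father-reared replicates 15 and 16 (exact permutation p = 0.205). Within each of the 3 stretches of library numbers taken as candidate batches the share was higher in father-reared fish, by 0.186 percentage points in the earliest stretch. Total counts were 4677000 ± 1322000 per fish in father-reared and 4981000 ± 896900 in orphaned families (n = 8 and 8, exact permutation p = 0.600, adjusted p = 0.800).

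**Figure D1:**
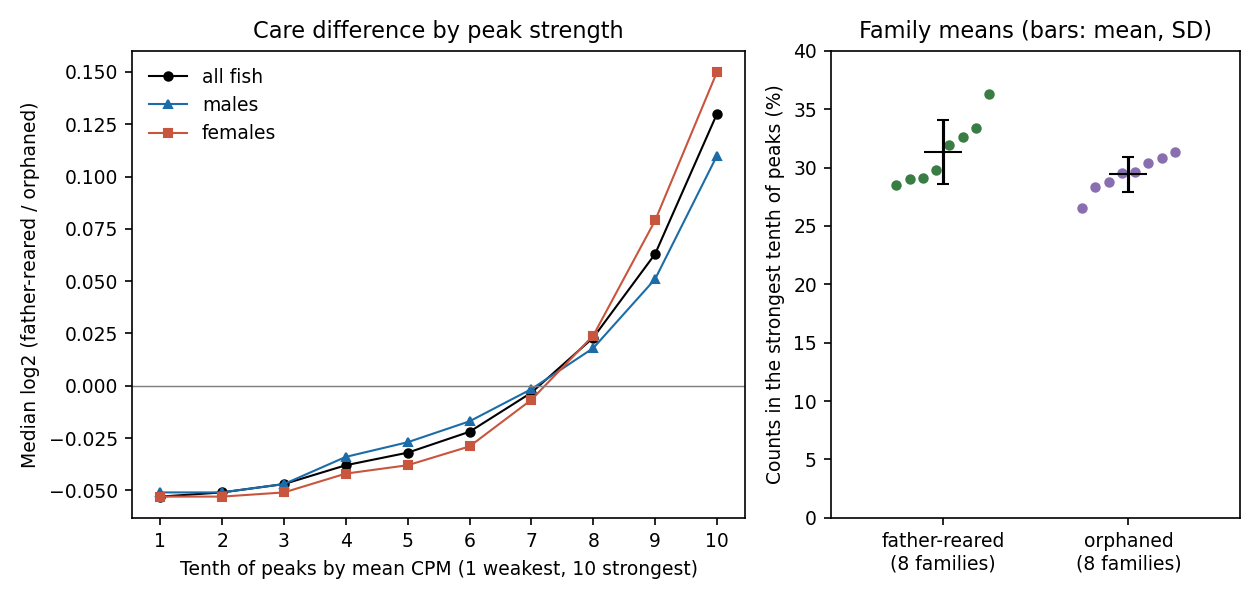
Left, the median log2 ratio of father-reared to orphaned fish (y axis) in each 10% of peaks ranked by mean CPM (x axis), for all fish, males and females; right, the share of counts in the strongest 10% of peaks per family, with mean and SD. The median for all fish runs from -0.05 in the weakest 10% to 0.13 in the strongest, and the family values of the 2 groups overlap.

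Care was then compared within each sex. In males no peak passed, with 5352 peaks at a raw p under 0.05 and a lowest edgeR adjusted p of 0.13 (DESeq2: 0 peaks, 5035 at a raw p under 0.05, lowest adjusted p 0.069). The peak with the lowest p was scaffold_89 10177 to 10577, at 11.9 ± 10.0 CPM (n = 8) in father-reared and 0.258 ± 0.261 CPM (n = 7) in orphaned males, a log2 difference of 5.25 (SE 0.97, edgeR adjusted p = 0.13). The next was scaffold_47 1119029 to 1119429, at 8.17 ± 2.42 CPM (n = 8) against 4.53 ± 0.847 CPM (n = 7), a log2 difference of 0.88 (SE 0.17, edgeR adjusted p = 0.25). The other 8 of the 10 lowest had adjusted p values of 0.92, among them groupXX 4226119 (log2 0.50) and groupV 6044666 (log2 -0.59). The scaffold_89 peak passed when any of father-reared replicates 1, 11 and 12 or orphaned replicate 7 was left out, with edgeR adjusted p values of 0.029, 0.028, 0.0042 and 0.00061. Father-reared replicates 1 and 11 are males with 0.473 and 0.489 CPM at this peak. Father-reared replicate 12 and orphaned replicate 7 are females outside this contrast, with 22.5 and 22.2 CPM. Without either female the log2 difference stayed at 5.25, so those passes came through the spread estimated over all fish. The peak at scaffold_47 1119029 also passed without father-reared replicate 11.

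In females no peak passed either, with 4667 peaks at a raw p under 0.05 and a lowest edgeR adjusted p of 0.92 (DESeq2: 0 peaks, 4451 at a raw p under 0.05). The lowest raw p belonged to groupVII 6676227 to 6676627, at 11.2 ± 2.05 CPM in father-reared and 7.53 ± 1.35 CPM in orphaned females (n = 8 and 8), a log2 difference of 0.56 (SE 0.12, edgeR adjusted p = 0.92). The next were groupXIII 15207700 to 15208100 (log2 -0.57, SE 0.13) and groupIV 7965129 to 7965529 (log2 0.53, SE 0.12), both with the same adjusted p. The 95% interval lay within 1.5-fold for 87.6% of peaks in males and 91.1% in females. Simulated 1.5-fold changes were recovered at 44.8% in males and 52.2% in females.

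The difference of the care effect between the sexes was tested directly and no peak passed, with 3519 peaks at a raw p under 0.05 and a lowest edgeR adjusted p of 1 (DESeq2: 0 peaks, 3165 at a raw p under 0.05). The lowest raw p belonged to groupI 4007921 to 4008321, where father-reared males had 3.72 ± 0.960 CPM (n = 8) against 5.16 ± 0.698 CPM (n = 7) in orphaned males, and father-reared females 5.08 ± 0.581 CPM against 3.34 ± 0.774 CPM in orphaned females (n = 8 and 8), an interaction of -1.09 on the log2 scale (SE 0.25, edgeR adjusted p = 1). The intervals were wide for this contrast, within 1.5-fold for 56.7% of peaks and within 2-fold for 97.3%. Simulated interactions were recovered at 10.4% for 1.5-fold and 65.2% for 2-fold changes. Without father-reared replicate 12 the scaffold_89 peak passed (log2 8.35, adjusted p = 0.0040).

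Males and females differed strongly, and mostly on groupXIX, the chromosome that carries the sex-determining region of this species (males XY, females XX). The test of sex called 2337 peaks. Of these 2169 lay on groupXIX, 49.9% of the 4345 peaks tested there, with 2075 lower and 94 higher in males. On the rest of the genome 168 peaks were called, 147 higher and 21 lower in males. The count of 21 was 35 without father-reared replicate 5 or orphaned replicate 10, 14 without father-reared replicate 4 or 16 or orphaned replicate 14, and 43 with family as a fixed replicate block. The odds ratio of a call on groupXIX against elsewhere was 571 by Fisher's exact test, whose p was below the smallest number the software represents.

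The sex given for each fish was matched by its groupXIX share of counts. It was 3.53% ± 0.0716 in males (SD, n = 15) and 4.47% ± 0.0394 in females (SD, n = 16). The highest male stood at 3.66% and the lowest female at 4.39%. In 15 of 15 families with both sexes the brother lay below the sister (two-sided exact sign-flip permutation p = 6.1e-05, the smallest that 32768 arrangements allow).

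**Figure D2:**
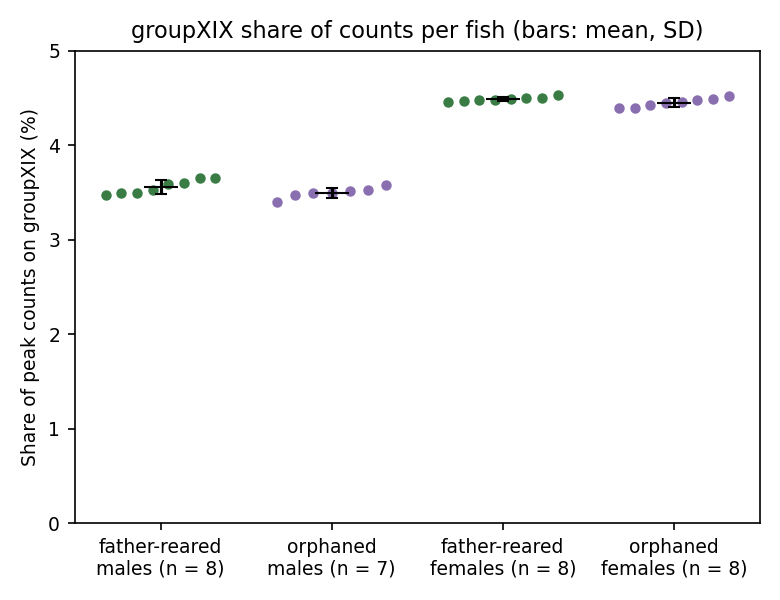
Share of all peak counts that fell on groupXIX (y axis, %) for each fish, split by sex and care (x axis), with mean and SD. All males lie at or below 3.66% and all females at or above 4.39%, in both care groups.

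The lower counts in males were uneven along groupXIX. Males are XY and females XX, and counts were not corrected for copies of the X. A lower count in males there need not mean less open chromatin. Relative to females and scaled to counts off groupXIX, males had 1.02 ± 0.04 of the female mean from 0 to 2 Mb (SD, n = 15, exact sign-flip permutation p = 0.051) and 0.906 ± 0.053 from 2 to 4 Mb (p = 0.000183, permutation). From 4 to 12 Mb the ratio was 0.560 ± 0.011 (SD, n = 15, exact permutation p = 6.1e-05). In that stretch 1573 of 1684 peaks (93.4%) were called lower in males, with a median log2 difference of -0.95. From 12 Mb to the end the ratio was 0.923 ± 0.014 (p = 6.1e-05, permutation), with 428 peaks lower and 86 higher in males of 1879. These 4 stretches were set after the windows had been seen. In 1 Mb windows the ratio went from 0.872 ± 0.039 between 3 and 4 Mb to 0.507 ± 0.019 between 4 and 5 Mb, and from 0.573 ± 0.013 between 11 and 12 Mb to 0.875 ± 0.013 between 12 and 13 Mb.

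**Figure D3:**
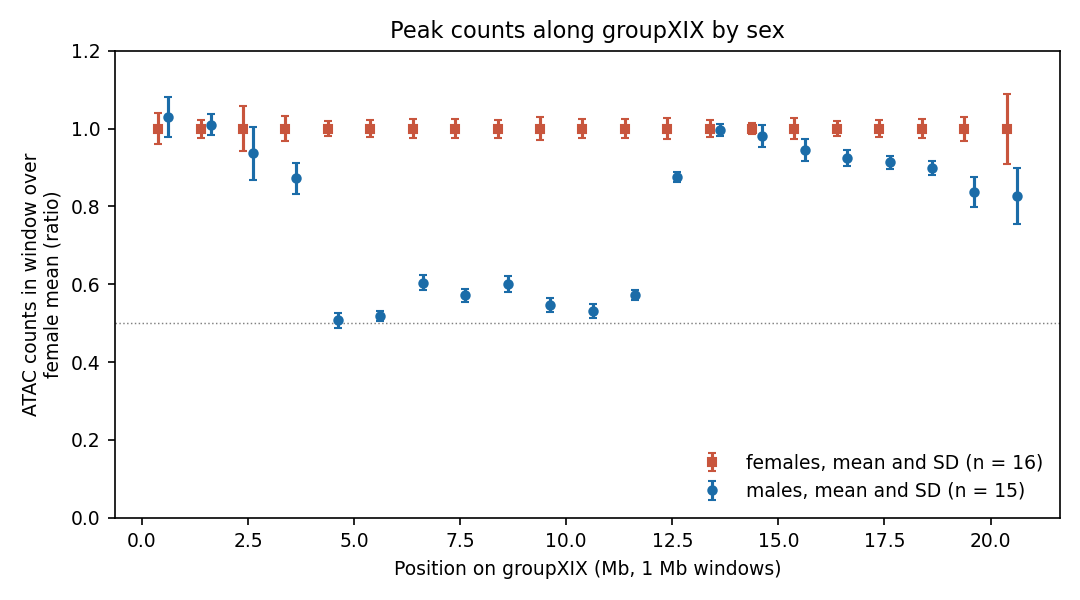
Counts per 1 Mb window of groupXIX (x axis, Mb) in males, as a ratio to the female mean (y axis), with SD over fish; squares at 1 carry the SD of females, and the dotted line marks 0.5. The ratio in males lies between 0.507 and 0.604 in the windows from 4 to 12 Mb and between 0.827 and 1.03 in the others.

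The named peaks of groupXIX showed both directions. The lowest in males by log2 was groupXIX 19958361 to 19958761, at 2.85 ± 4.77 CPM in males (n = 15) and 9.54 ± 9.17 CPM in females (n = 16), a log2 difference of -1.66 (SE 0.44, edgeR adjusted p = 0.019) that did not pass without father-reared replicate 2 (adjusted p = 0.074), orphaned replicate 2 (0.11) or orphaned replicate 11 (0.056). It was followed by groupXIX 4743876, at 2.07 ± 0.548 CPM against 5.89 ± 1.09 CPM (n = 15 and 16, log2 -1.50, edgeR adjusted p = 7.3e-13), and by groupXIX 9201374, groupXIX 8349328 and groupXIX 8438158 with log2 differences of -1.40, -1.39 and -1.36. The peaks higher in males were led by groupXIX 415478 (log2 1.58) and groupXIX 420676 to 421076, at 12.0 ± 4.95 CPM in males and 3.80 ± 2.64 CPM in females (edgeR adjusted p = 1.9e-09). Then came groupXIX 14092512, groupXIX 18078143 and groupXIX 18670782, with log2 differences of 0.84, 0.78 and 0.74.

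Off groupXIX the calls leaned to males, above all the large ones. At a fold of 2 or more, 44 peaks were higher and 1 lower in males. These 44 lay on 13 linkage groups (28 peaks) and 11 scaffolds (16 peaks). Scaffolds held 7997 of the 96463 peaks tested off groupXIX. They held more than that share of the 44, and of all calls there, with 45 of the 147 higher and 6 of the 21 lower in males. In 17 of the 44 every male library exceeded every female library. With groupXIX left out before filtering, scaling and adjustment, 86 higher and 2 lower peaks passed in place of 147 and 21, and all 44 with a fold of 2 or more were among the 86. With the fit unchanged and only its p values adjusted over peaks off groupXIX, 89 higher and 2 lower passed.

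The strongest was groupX 741348 to 741748, at 12.8 ± 2.76 CPM in males (n = 15) and 0.899 ± 0.666 CPM in females (n = 16), a log2 difference of 3.79 (SE 0.18, edgeR adjusted p = 1.6e-24). A neighbour at groupX 743083 to 743483 had 7.65 ± 2.12 CPM against 0.741 ± 0.575 CPM (log2 3.30, SE 0.21, edgeR adjusted p = 2.1e-18). Next were groupXI 4462164 to 4462564 (log2 3.25, SE 0.33), groupIII 15591825 to 15592225 (log2 3.24, SE 0.26) and groupVII 8638901 to 8639301 (log2 3.07, SE 0.27). The 5 lowest in males were scaffold_858 5856 (log2 -1.29, adjusted p = 8.9e-10), scaffold_858 6578 (log2 -0.88, adjusted p = 2.6e-05), scaffold_654 5036 (log2 -0.56), groupX 14661844 (log2 -0.51) and groupXV 6826601 (log2 -0.45). The last 3 did not pass with groupXIX left out, with edgeR adjusted p values of 0.063, 0.071 and 0.19.

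**Figure D4:**
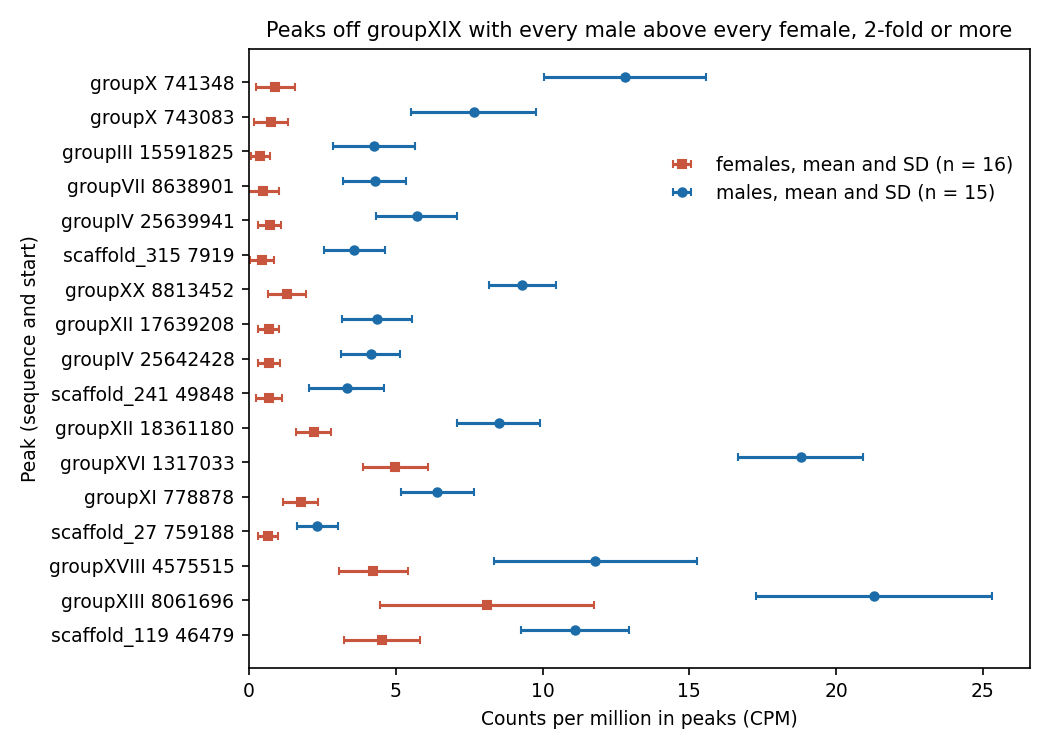
Mean CPM and SD over fish (x axis) in males and females for the 17 peaks off groupXIX (y axis, sequence and start) that were at least 2-fold higher in males with every male above every female. The largest log2 difference is at groupX 741348, 12.8 CPM in males against 0.899 CPM in females.

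The side of the brain was compared as a check, since 13 libraries came from left and 18 from right sides. No peak passed, with 4089 at a raw p under 0.05 and a lowest edgeR adjusted p of 0.99 (DESeq2: 0 peaks, 3986 at a raw p under 0.05). The lowest raw p belonged to groupXIII 15063779 to 15064179, at 8.42 ± 1.14 CPM on the left (n = 13) and 6.28 ± 1.49 CPM on the right (n = 18), a log2 difference of 0.45 (SE 0.10, edgeR adjusted p = 0.99). The other peaks with the lowest raw p were scaffold_54 1119512 (log2 0.52), scaffold_1240 3458 (log2 -1.57), groupXIX 12988619 (log2 -0.51) and groupIV 13022725 (log2 0.39), all with the same adjusted p. For 98.5% of peaks the 95% interval of the left to right ratio lay within 1.5-fold.

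Fish of 1 family resembled each other in part of the genome. Over all 96463 peaks tested off groupXIX, brother and sister deviated from their group means with a mean correlation of 0.0706 (SD 0.14, 15 pairs), against -0.00989 for males and females of the same care group with different leading numbers (105 pairs), some of which may be half-siblings since the relation between families is not given. This excess of 0.0805 did not pass (two-sided permutation p = 0.0734, 100000 resamples). In the 5000 most variable peaks the mean was 0.248 (SD 0.11) against -0.0352, with a positive correlation in 14 of 15 pairs (permutation p = 1e-05, the smallest the resamples allow). These correlations run across peaks, which are not independent replicates, and the permutations exchanged families, not peaks.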

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

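The tests of a chance difference between families, of library neighbours in the 500 most variable peaks, of male-higher counts at a fixed raw p and of the direction of 2-fold peaks, and the adjustment of p values off groupXIX alone, were chosen after the result was seen. The test of shared genotype in the 500 most variable peaks was set before its result but after the data were seen. The other tests were set before the result.

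Single fish or families stood apart in 9 of 82 groups examined. Chance alone gives about 5% in groups not chosen by their values. Most groups here belong to peaks picked for a low raw p in these same fish, so that rate is not a fair benchmark. In females, groupV 1945222 was at 5.04 CPM in orphaned replicate 6 against 7.95 to 8.95 CPM in the other orphaned females. The peak at groupIX 1559023 was at 9.82 CPM in father-reared replicate 4 against 12.4 to 13.8 CPM. In males, groupI 4007921 was at 6.57 CPM in orphaned replicate 14 against 4.53 to 5.36 CPM. The peak at groupIV 941616 was at 12.3 CPM in orphaned replicate 9 against 7.47 to 9.62 CPM in the other orphaned females, and groupVIII 16147351 at 20.4 CPM in father-reared replicate 10 against 9.08 to 12.6 CPM in the other father-reared females. The scaffold_89 10177 peak was at 22.2 CPM in orphaned replicate 7 against 0.174 to 0.267 CPM in the other orphaned females, and at 22.5 CPM in father-reared replicate 12 against 0 to 1.38 CPM in the other father-reared females. Family F27 had a mean of 7436000 counts against 3089000 to 5134000 in the other father-reared families, and family F30 had counts in 99.93% of peaks against 99.85% to 99.88% in the other orphaned families.

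The first pattern weighed was the larger share of counts in the strongest 10% of peaks in father-reared libraries. Depth as the whole cause was argued against, since the difference adjusted for log total count was 2.3 percentage points (SE 1.09) against 1.92 unadjusted. Chance differences between families stay open (exact permutation p = 0.102). The place in the library series and the brain side cannot be told apart from care at this precision: the mean difference within library stretches was 1.91 over fish and the family difference adjusted for stretch 1.74 (SE 1.15), and that adjusted for side was 2.05 (SE 1.15), with 0.55 on the left (8 against 5 fish) and 3.37 on the right (8 against 10). Care itself stays among the open explanations, and the share ranged from 24.1% to 36.5% over the 31 fish. Library quality was not tested as a cause. Counts fell in a mean of 99.84% of peaks in father-reared and 99.88% in orphaned families (exact permutation p = 0.0622, adjusted p = 0.204).

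The second pattern was the likeness of siblings. Siblings had library numbers 1 or 2 apart, so shared handling was set against shared genotype. Library neighbours of different families exceeded other pairs of different families by -0.00052 (SE 0.022) over all peaks and by 0.019 (SE 0.025) in the 500 most variable peaks, which argues against place in the series as the main source. The sibling excess rose to 0.431 in those 500 peaks (permutation p = 1e-05, the smallest possible, positive in 15 of 15 pairs), as sequence variants shared by siblings could produce. This is a hypothesis, and shared tank or rearing conditions of a family stay open as untested.

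The third pattern was the excess of male-higher peaks off groupXIX. A lower groupXIX count in males could shift their scaling; the test written first was the number called with groupXIX left out, and at 86 against 147 it met the bound set for that explanation. That count falls to 89 from the adjustment alone, so it decides nothing, and at the fixed raw p of 0.00115 that bounds the calls 139 were higher and 34 lower in males against 147 and 21, with a median change of -0.01 in log2 of the 147: the excess is smaller but present, which argues against scaling as the whole cause and leaves a part open. Regulation that differs by sex stays open, since the 97.8% of 2-fold peaks that were higher in males restates the pattern. Reads from male-carried sequence that align elsewhere, such as Y copies absent from the assembly, may account for part of them. In 38.6% every male exceeded every female, which neither meets nor excludes what was set for that explanation. Of the 44 peaks, 16 had a female mean under 1 CPM, and low counts limit how fully the sexes can separate.

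Other splits of the samples were drawn 100 times per comparison. For the total of sex calls the splits argue against chance: 1 of 100, the real one, called as many as 2337 peaks. The highest other called 1109. These splits swapped the sexes within randomly chosen families. A split that swaps few or most families keeps part of the real difference, so 1109 may overstate what chance calls. Most of the 2337 lay on groupXIX, and the splits did not count calls off groupXIX separately, so they do not decide on those. For care chance cannot be excluded, with 7302 peaks at a raw p under 0.05 in the fit used for the splits, a highest other of 20840, and 24 splits with as many. In males the values were 5352, 11792 and 27, in females 4668, 20517 and 37, for the interaction 3519, 10844 and 37, and for side 4088, 17927 and 46. In 48 of the 100 care splits at least 1 peak was called, with up to 840, where the real split called 0. Fewer splits called any peak within males (10) and females (15), with at most 1 fish per family. For side, reassigned over single fish, 11 did. This points to a structure of the samples, and p values of the care fit over all fish may be too small. Siblings that deviate together are a candidate source that was not tested.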

How the results depend on the processing

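Alternatives planned before the data were examined and those added after are listed with the processing. The robust prior, trend removal, 2 libraries left out together, larger regions and 500 peaks were chosen after seeing the data. So were the strongest-peak share, its cutoffs, families left out, centring by sex and adjustment off groupXIX alone. The gene-list tests and the promoter windows were not run. For care, care in either sex, the interaction and side, the alternatives run in edgeR, DESeq2 and limma other than leaving out 1 library called 0 peaks. Over their alternatives, left-out libraries included, peaks at a raw p under 0.05 numbered 5470 to 11239 for care, 3821 to 6990 in males, 3482 to 8941 in females, 3030 to 4443 for the interaction and 3014 to 5218 for side. With 1 library left out the calls ran from 0 to 3 for care, 0 to 2 in males, 0 to 0 in females, 0 to 1 for the interaction and 0 to 0 for side. For care there were 3 calls without father-reared replicate 3 and 1 each without father-reared replicates 8 and 13 and orphaned replicate 7. In males there were 2 without father-reared replicate 11 and 1 each without father-reared replicates 1 and 12 and orphaned replicate 7, and for the interaction 1 without father-reared replicate 12.

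Sex calls ran from 2294 to 2362 with 1 library left out: male-lower on groupXIX from 2050 to 2074, male-higher there from 80 to 113, male-higher elsewhere from 129 to 158 and male-lower elsewhere from 14 (without father-reared replicates 4 or 16 or orphaned replicate 14) to 35 (without father-reared replicate 5 or orphaned replicate 10), against 21. DESeq2 called 2377 peaks, 2317 of them shared. With groupXIX left out, 88 peaks were called, 86 higher and 2 lower in males. With the fit unchanged and its p values adjusted over peaks off groupXIX alone, 91 were called, 89 higher and 2 lower, so most of the fall comes from the adjustment. Male-lower peaks elsewhere numbered 43 with family as a fixed replicate block and 57 at a threshold of 0.10; for the first the cause was not tested. With that replicate block, sex calls numbered 2382, 2300 of them shared.

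The groupXIX share by care was -0.0144 percentage points on family means (exact permutation p = 0.998) and 0.0181 over fish. The value on family means is shifted by sex, since 1 orphaned family is a lone female. Centred by sex, which removes that shift, it reversed to 0.0444 (exact permutation p = 0.0322). That p was not adjusted over the library measures, and the centring was chosen after the data were seen. The difference in the share of the strongest 10% of peaks ran from 1.21 to 2.32 with 1 family left out. The sibling excess of 0.0805 was 0.283 in the 5000 and 0.431 in the 500 most variable peaks, both past the threshold.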

Other observations

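The tests in this part were chosen after the data were seen, other than the calls for sex.

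The main axis of variation among libraries followed peak strength. Each fish gave 1 library, so differences between fish and between library preparations cannot be told apart here. The first principal component off groupXIX, after removing group means, held 18.5% of the variance, and it correlated with the share of counts in the strongest 10% of peaks over the 31 fish (Pearson's r = 0.927 and Spearman's rho = 0.913 in size, permutation p = 1e-05 for each, the smallest possible). Without the 2 fish farthest from the median share, r was 0.910.

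Of the 12 most variable peaks off groupXIX, 9 were under 1 CPM in some fish and the other 3 in none. The peak at groupXI 4373588 to 4374371 ranged from 0 to 123 CPM with 16 of 31 libraries under 1 CPM, and peaks near it at groupXI 4353453 and groupXI 4374647 were under 1 CPM in 23 and 20 libraries. All 3 were highest in orphaned replicate 9. The peaks at scaffold_95 140288 and scaffold_95 143379 were over 1 CPM in all fish, with medians of 15.4 and 13.1 CPM but 510 and 468 CPM in orphaned replicate 15. At scaffold_89 10177, the peak with the lowest p for care in males, fish fell into 2 sets: 5 of 8 father-reared males, 1 of 8 father-reared females and 1 of 8 orphaned females had over 10 CPM, and the highest of the other fish had 1.38 CPM.

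Male-higher peaks off groupXIX lay in clusters. Of the 147, 43 had another within 10 kb, where 10000 random sets of peaks off groupXIX of the same size had a median of 0 and at most 10. The random sets were not matched for the share of peaks on scaffolds or for local peak density, so part of the contrast may come from that. Examples are groupX 741348 and 743083, groupIV 25639941 and 25642428, groupXVI 1317033 and 1318065, 3 peaks of scaffold_27 from 757394 to 759188, and 4 peaks of scaffold_119 from 46479 to 56101. Summed over whole scaffolds, 2 of the 160 with at least 5 peaks passed, both higher in males: scaffold_108 (210.5 ± 13.6 CPM in 15 males and 186.2 ± 16.1 CPM in 16 females, exact permutation p = 0.000244, adjusted p = 0.0391) and scaffold_167 (126.2 ± 9.01 and 112.6 ± 10.3 CPM, exact permutation p = 0.000549, adjusted p = 0.0439).

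Within groupXIX, 73 of the 75 windows of 100 kb between 4 and 12 Mb had a median log2 difference under -0.6, and 7 of the 117 others did. Beyond 12 Mb the 428 male-lower peaks had a median log2 of -0.78 and the 86 male-higher peaks of 0.41.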
